A study of Mus musculus with 60 samples.

How the data were processed

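Whole organs of 6 male mice, 3 Ftsj1-deficient and 3 wildtype, were sampled at 4 months of age. Per the labels, 2 mice were brothers of 1 litter and 4 of another, each litter holding both genotypes, and all libraries carry the same batch label. Per the labels' protocols, mice were fed ad libitum, tissue was frozen on dry ice and pulverised, RNA was extracted with phenol, and 30 stranded poly-A libraries and 30 stranded total RNA libraries were prepared. The rRNA depletion of the latter is per the series' title. The submitters' processing notes name the genome build GRCm39, featureCounts, Subread 2.0.3 and DESeq2. Alignment settings, the annotation and whether counting used the strand or spread reads over several places are not given in the sources used here. Reads of near-identical genes and of overlapping or antisense genes are therefore uncertain throughout.

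The 25 deposited tables, 1 for each organ and each of 5 kinds of feature (poly-A genes, lncRNAs, snoRNAs, snRNAs and tRNAs), hold the authors' comparison of the 2 genotypes and no value per library. The column of mean signal over the 6 libraries was deposited by the authors as DESeq2's mean of normalised counts, per the file headers. The deposited log2 fold change is signed as Ftsj1-deficient minus wildtype, which the sign of Ftsj1 in all 5 poly-A tables shows, and its standard error is in log2 units as well. The authors' test score is the Wald statistic, and it equalled the deposited log2 fold change divided by its standard error within rounding. The deposited p-value and adjusted p-value columns are DESeq2's, the second by the Benjamini-Hochberg method, and the authors left the adjusted value empty for features removed by independent filtering or as count outliers. Fold changes in these tables are not shrunk, so that genes at low level can carry very large ones. Poly-A, lncRNA and snoRNA tables each hold 1 entry with an empty name, which was left out and took at most 0.00187% of the summed level. tRNA features carry RNAcentral identifiers without names, so no test by amino acid or for mitochondrial tRNAs was made. Depth per library is unknown; ratios of size factors were recovered from the lowest mean levels, which are those of features with 1 read in 1 library. The product of the 6 factors, which should be close to 1, was between 1.02 and 1.06 in the poly-A tables and further from 1 in some of the others, so only poly-A factors are reported.

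No count model was fitted, since counts per library were not used here: a feature counts as risen or fallen when the authors' adjusted p was under 0.05, by the sign of its log2 fold change. The design, fixed before the data were examined, gave this rule for tables that hold only the authors' comparison, along with the gene lists and the rule for which genes are named. The rule for named genes took Ftsj1 in every organ, up to 12 poly-A genes and up to 5 non-coding features per direction and organ with the largest fold changes among those past the threshold at a mean level of 10 or more, the 3 smallest p where fewer than 3 passed, up to 10 features called in 3 or more organs, and up to 4 called members per list. The text leaves out some of the features that this rule names. Cyp4a10, Cyp4a31, Cyp4a14, Fgf21, Pdk4, Angptl4, Acot2, Srebf1, Acly, Acss2 and Thrsp are given in both kidney and liver for the plot of lipid genes, a choice made after their values were seen, as was the naming of list or overlap members without a value. Coordinates of the build used by the authors were not at hand, so none are printed.

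Gene lists (53, each assigned to all organs or to those it fits) were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistics of genes with a mean level of 10 or more, with a preset inter-gene correlation of 0.01 and lists of at least 3 genes, and adjusted over the lists of an organ by Benjamini-Hochberg. An estimated correlation needs values per library and could not be had; a preset correlation of 0.05 was tried instead, and of the lists that passed 6 of 7 in brain, 14 of 16 in heart, 13 of 15 in kidney, 10 of 13 in liver and 13 of 16 in spleen still passed. For no passing list did the median, the mean and the test differ in sign. List medians were also set against 10000 random lists matched on level in 20 bins, and did not stand out (p of 0.05 or more) for 6 of the lists and classes that passed. Symbols were matched directly (1186) or by synonym (33) through RefSeq names of another assembly, GRCm38.p6, 3 were duplicates and 7 were not matched. Of the 1169 list members that the poly-A tables name, 43 are listed at 0 in every organ, among them Actc1, Tnnc1, Pln, Alas2, Per3, Ciart and Xist, for a reason not given in the sources used here, and such genes could not be tested. For snoRNAs and snRNAs, classes were taken from the names (C/D box, H/ACA box, U1, minor spliceosome and predicted genes).

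Differences between organs were tested per feature with Cochran's Q on the 5 log2 fold changes and their standard errors (4 degrees of freedom, features with a mean level of 10 or more in every organ), adjusted by Benjamini-Hochberg per kind. This test treats organs as independent although they share mice. Overlaps of calls between pairs of organs used Fisher's exact test per direction, with Ftsj1 left out and features tested in both organs as background. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

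The calling rule, Cochran's Q, cameraPR and the recovery of size factors were tested on simulated data, and the overlaps, random lists, clock gene permutation and comparison of library kinds were not. With 200 genes given known changes at the real standard errors, the rule called 60% of genes with a log2 change of 1 in brain, 55% in heart, 68% in kidney, 74% in liver and 63% in spleen, and 84%, 79%, 87%, 92% and 88% of those with a log2 change of 2. Calls on unchanged genes made up 7.10%, 8.84%, 6.63%, 5.14% and 6.79% of its calls in the same order. Each share came from 1 simulated draw, so its place above the nominal 5% may be sampling error. Cochran's Q gave p under 0.05 for 5.03% of 17391 simulated genes that shared 1 common change, and cameraPR for 2.6% of 500 unshifted lists of 25 genes. Simulated values were independent between genes, and for Cochran's Q between organs. These rates therefore do not cover lists whose genes move together, or organs that share mice. For the calling rule, errors were normal and drawn at the standard errors that the test then used. Error rates and power of DESeq2's own fit and independent filtering were not simulated. Alternatives tried were adjustment over every feature with a p-value, over features with a mean level of 10 or more and over the 5 organs together, rank-based cameraPR, all features as background, other thresholds for overlaps, a mean level of 100 for lncRNAs in both library kinds, and, chosen after seeing the data, tRNA entries with identical values taken once.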

Results

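Ftsj1 is an X-linked gene whose protein methylates ribose in the anticodon loop of several tRNAs. RNA was measured in whole brain, heart, kidney, liver and spleen of 3 Ftsj1-deficient and 3 wildtype male mice aged 4 months. The question put by the study's title is which coding and non-coding RNAs differ between the genotypes in each organ. Each organ of each mouse gave a poly-A library, which holds mainly messenger RNA, and a library of total RNA depleted of ribosomal RNA, so that 60 libraries fell into 20 groups of 3. Every comparison below is Ftsj1-deficient minus wildtype within 1 organ, with n = 3 mice against 3. Errors of single features are the standard errors of log2 fold changes in the authors' tables. For gene lists, cameraPR treats the genes of a list as nearly independent (preset correlation of 0.01). Its p-values therefore do not measure the spread of a list among mice. A difference in 1 or few libraries that many genes of a list share can make them very small. The deposited tables give a mean level over the 6 libraries of an organ and no value per mouse, so the total count of each library is unknown. Mean levels of the poly-A tables, in units of 1e6 normalised counts, summed to 226 in brain, 141 in heart, 338 in kidney, 240 in liver and 128 in spleen. The largest of the 6 poly-A size factors exceeded the smallest 6.46 times in brain, 11.4 times in heart, 18 times in kidney, 4.80 times in liver and 2.14 times in spleen. These factors were recovered from the spacing of the lowest mean levels, and which mouse had which cannot be read from the tables.

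Ftsj1 mRNA was reduced in all 5 organs of the deficient mice. By the authors' deposited table its level was 15.4% of wildtype in brain, 9.75% in heart, 14% in kidney, 8.79% in liver and 8.98% in spleen. Log2 fold changes in the authors' deposited table were -2.70 ± 0.10, -3.36 ± 0.28, -2.84 ± 0.13, -3.51 ± 0.15 and -3.48 ± 0.18 and adjusted p of 3.89e-157, 4.69e-29, 4.16e-97, 4.65e-115 and 4.28e-79. The sign of the deposited fold changes was read from Ftsj1 itself. The direction of its change is therefore no separate result, while its size and the shared sign over the organs are. Which part of the gene was altered, and whether the remaining transcripts cover it, is not given in the sources used here. Of the genes next to Ftsj1 on the X chromosome, 29 were testable in brain, 27 in heart, 26 in kidney, 25 in liver and 28 in spleen. None of them passed DESeq2's adjusted p of 0.05 in any organ, and 0, 3, 2, 4 and 0 had an unadjusted p under 0.05. Enzymes that modify tRNA, Ftsj1 left out, had 0 of 74 tested members passing in brain and 0 of 73 in each other organ, and the list did not pass cameraPR (adjusted p from 0.0806 in heart to 0.938 in kidney). In heart the list was higher by ranks (adjusted p = 0.0339) and with all features as background (0.0226). Aminoacyl-tRNA synthetases had 0 of 21 members passing. Their list did not pass, with adjusted p of 0.0757 in spleen and 0.0806 in heart. By ranks it was higher in both (0.0300 and 0.0455), as it was with all features (0.0176 and 0.0226).

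Liver had the most poly-A genes past the authors' threshold and brain the fewest. By the authors' deposited table, 13 genes passed in brain (3 rose, 10 fell), 116 in heart (45 rose, 71 fell), 230 in kidney (79 rose, 151 fell), 419 in liver (162 rose, 257 fell) and 17 in spleen (11 rose, 6 fell), Ftsj1 included. At an unadjusted p under 0.05 the counts were 802, 1842, 1407, 2122 and 1539 in the same order. With Benjamini-Hochberg adjustment over the 5 organs together, 20 genes passed in brain, 251 in liver and 33 in spleen.

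**Figure D1:**
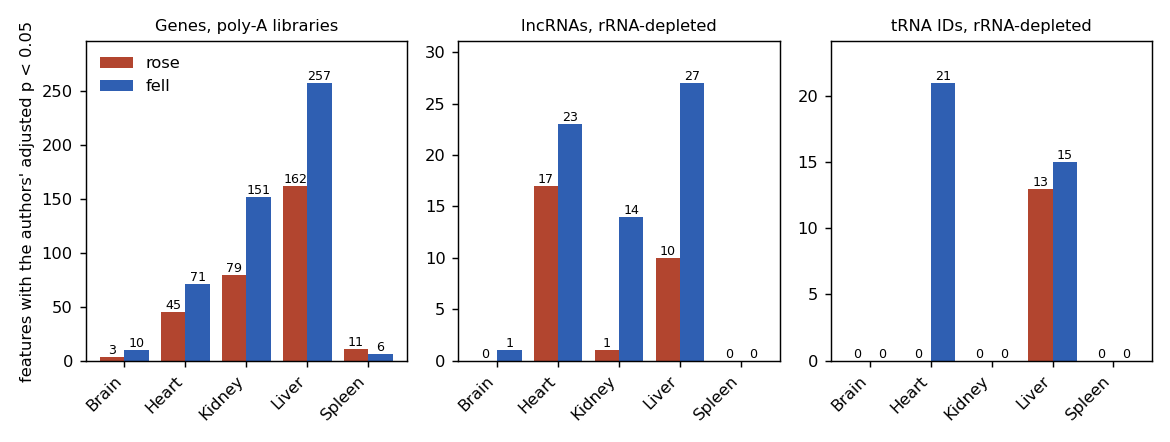
Number of features past the authors' adjusted p of 0.05 that rose or fell in the Ftsj1-deficient mice, for each organ (n = 3 mice against 3), with separate vertical scales for poly-A genes, lncRNAs and tRNA identifiers. Poly-A calls were most numerous in liver (162 rose, 257 fell), and tRNA calls came from heart (21 fell) and liver (13 rose, 15 fell).

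Genes induced by neuronal activity were lower in the brain of the deficient mice. The immediate early genes are switched on within minutes of a stimulus, and 7 of 26 tested members fell while 19 did not pass. The matricellular protein gene Ccn1, the synaptic plasticity gene Arc and the transcription factor genes Fos and Egr4 were among them, with log2 fold changes of -0.94 ± 0.17, -0.81 ± 0.15, -0.75 ± 0.16 and -0.44 ± 0.085 in the authors' deposited table. Btg2, Ier2 and Junb fell as well, by 0.74, 0.68 and 0.56 on the log2 scale (adjusted p = 4.67e-05, 0.00997 and 0.00339 in the authors' deposited table). Adjusted over the list alone, 14 members fell. The list's median was -0.34, and cameraPR placed it below the other genes (adjusted p = 1.90e-39). Outside this list Stoml3, which encodes a membrane protein of sensory neurons, and Lgr6, a receptor for R-spondins, fell (log2 fold changes -1.44 ± 0.34 and -0.46 ± 0.11 in the authors' deposited table).

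The stress regulator Nupr1 and the transcription factor gene Atf5 rose in brain, with log2 fold changes of 0.89 ± 0.11 and 0.64 ± 0.14 and adjusted p of 6.66e-12 and 0.00592 in the authors' deposited table. Both belong to the ATF4 targets, genes induced in the integrated stress response, of which 2 of 24 rose and 22 did not pass (median 0.10, cameraPR adjusted p = 4.93e-06). Gm5619 was the remaining gene that rose (0.60 ± 0.14 in the authors' deposited table). Interferon-stimulated genes had 0 of 33 members passing over all genes and 12 that rose when adjusted over the list alone. The list was higher (median 0.46, adjusted p = 6.73e-19 by cameraPR). Ribosomal protein genes and nuclear genes of the respiratory chain were slightly lower, with medians of -0.11 and -0.077 and no member passing of 76 and 72 (adjusted p = 2.29e-06 and 6.93e-05). Nuclear and imprinted long non-coding RNAs were higher as a list (median 0.14, 0 of 21 passing, adjusted p = 0.000577). Glucocorticoid targets were lower (median -0.089, 0 of 18, adjusted p = 0.0173), and this call was lost with a preset correlation of 0.05 (adjusted p = 0.10). Synaptic, myelin, astrocyte, microglia and choroid plexus genes had no member passing and lists that did not pass, with medians of 0.040, -0.010, -0.027, -0.014 and 0.035. Striatal markers had 0 of 13 members passing, all of them above 0, and a median of 0.12. Their list did not pass (adjusted p = 0.0503), but was higher by ranks (0.0113) and with all features as background (0.0238). Pituitary markers, with 5 members tested, had a median of -1.14 and did not pass (adjusted p = 0.462). In all, 7 of 35 lists passed in brain.

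Transcripts of neutrophils were higher in the heart of the deficient mice. Of the neutrophil markers 4 of 11 rose and 7 did not pass: the chemokine receptor gene Cxcr2, the calprotectin genes S100a9 and S100a8, and Csf3r, the receptor for granulocyte colony-stimulating factor. Their log2 fold changes were 2.27 ± 0.35, 2.26 ± 0.37, 1.83 ± 0.44 and 0.68 ± 0.18 in the authors' deposited table, with adjusted p of 9.83e-07, 3.53e-06, 0.0154 and 0.0397. As a list they were higher (median 1.57, cameraPR adjusted p = 2.84e-07). Interferon-stimulated genes were also higher, with 3 of 33 members rising (Irf7 0.77 ± 0.20, Isg15 0.74 ± 0.20 and Oas1a 0.71 ± 0.18 in the authors' deposited table). When adjusted over the list alone 8 rose, and the median was 0.35 (adjusted p = 2.13e-14). Slfn4, a Schlafen family gene of myeloid cells, and Slc51a, which encodes a subunit of a bile acid transporter, rose by 1.30 and 1.45 on the log2 scale by the authors' deposited table. Erythroid genes were higher beside them (median 0.25, 0 of 19 passing, adjusted p = 0.0107), a call that a preset correlation of 0.05 ended (adjusted p = 0.0539).

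Pdk4 and Angptl4 rose and Per1 and Ankrd1 fell in heart. Pdk4, which restrains glucose oxidation by inhibiting pyruvate dehydrogenase, and Angptl4, an inhibitor of lipoprotein lipase, had log2 fold changes of 1.09 ± 0.24 and 1.31 ± 0.25 in the authors' deposited table. The PPAR alpha targets, to which both belong, had 2 members rising, 1 falling and 22 not passing, and the list did not pass (median 0.051, mean of opposite sign, adjusted p = 0.582). Per1, a core gene of the circadian clock, and Ankrd1, a stress-responsive gene of cardiomyocytes, fell by 1.12 and 0.78 on the log2 scale by the authors' deposited table (adjusted p = 9.83e-07 and 0.00924). Each was the only member passing of its list, and both lists were lower. Clock genes had a median of -0.37 over 17 genes (adjusted p = 0.00101, or 0.0671 by ranks). Of them 6 lay above 0 and, adjusted over the list alone, 3 rose and 5 fell. Cardiac stress genes had a median of -0.22 over 14 (adjusted p = 0.000138). Hsd17b7 of cholesterol synthesis, Ndufs5 of respiratory complex I and the host transcript Snhg8 rose, and the imprinted transcript Meg3 fell (log2 fold changes 0.70 ± 0.13, 0.66 ± 0.18, 0.96 ± 0.24 and -0.63 ± 0.12 in the authors' deposited table). Ribosomal protein genes (median 0.30), nuclear respiratory chain genes (0.27), proliferation genes (0.39) and small nucleolar RNA host genes (0.15) were higher as lists, with 0, 1, 0 and 1 members passing (adjusted p = 3.30e-14, 1.08e-10, 2.20e-07 and 0.00498). Mitochondrially encoded genes (median -0.19), extracellular matrix genes (-0.10) and immediate early genes (-0.17) were lower with no member passing (adjusted p = 0.0134, 0.00454 and 0.0228). The last of these calls was lost at a preset correlation of 0.05 (adjusted p = 0.112).

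Lep, Slco1b2, Bhmt and Isl1 were among the largest falls in heart. The adipocyte hormone gene Lep, the hepatocyte genes Slco1b2 and Bhmt, and Isl1, a transcription factor gene of cardiac progenitors and the sinus node, had log2 fold changes of -4.92 ± 0.85, -5.31 ± 1.33, -4.89 ± 1.18 and -4.06 ± 0.97 in the authors' deposited table. Serpina3b fell as well (-6.61 ± 1.55 in the authors' deposited table), along with the antibody constant region gene Ighg3 and 5 variable segments, led by Ighv9-3 (-7.29 ± 1.45). Variable segments share reads with near-identical ones and are uncertain. Mean levels of these genes lay between 12.7 and 68.4 normalised counts in the authors' deposited table. Levels near 0 in the libraries of 1 genotype therefore cannot be excluded, and the fitted folds are no bounds. Adipocyte markers were lower with 1 of 15 falling (median -1.84) and hepatocyte secreted proteins with 0 of 16 (3 adjusted over the list alone, median -2.73). Lung epithelium markers were lower with 0 of 8 passing (median -7.98). The adjusted p of these lists by cameraPR were 1.14e-07, 1.94e-09 and 3.14e-13. With no value per mouse, fat, liver or lung tissue left in few libraries cannot be told apart from an effect of the genotype. Fatty acid synthesis genes, which share Thrsp with the adipocyte markers, were lower beside them with no member passing (median -0.21, adjusted p = 0.00113). Cardiomyocyte contractile genes had 0 of 20 members passing and skeletal muscle markers 0 of 12 (adjusted p = 0.924 and 0.630). In all, 16 of 30 lists passed in heart.

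Targets of PPAR alpha, the nuclear receptor that switches on fatty acid oxidation, rose in the kidney of the deficient mice. Of 29 tested members 11 rose, none fell and 18 did not pass, and 20 rose when adjusted over the list alone. Pdk4, Angptl4 and the acyl-CoA thioesterase gene Acot2 had log2 fold changes of 1.09 ± 0.12, 0.73 ± 0.12 and 0.52 ± 0.10 in the authors' deposited table (adjusted p = 8.83e-16, 2.83e-07 and 3.79e-05). Cyp4a10, Cyp4a31, Acot1, Acot3, Vnn1, Ehhadh and Hadha were among the other members that rose, and the Cyp4a and Acot genes have close paralogs with which they may share reads. The list's median was 0.32 (cameraPR adjusted p = 1.60e-41). Fatty acid elongation genes Elovl3 and Elovl6 and the carboxylase gene Acacb rose (3.65 ± 0.89, 0.55 ± 0.11 and 0.44 ± 0.11 in the authors' deposited table). Fatty acid synthesis genes were higher with 2 of 18 rising (median 0.18, adjusted p = 0.00764, or 0.137 by ranks).

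The largest falls in kidney included Synpr, a synaptic vesicle protein gene, Cntnap5a, a gene of the neurexin family, Skint11 and Zfp600, with log2 fold changes of -2.79 ± 0.33, -2.40 ± 0.20, -2.15 ± 0.25 and -2.58 ± 0.58 in the authors' deposited table. The acute phase gene Saa3 and 5 immunoglobulin segments, whose reads are shared among near-identical copies, fell as well (Saa3 -3.19 ± 0.82 in the authors' deposited table, at a mean level of 26 normalised counts). Lpo, which encodes lactoperoxidase, Atp12a, a proton pump subunit gene, Mybpc3, known from cardiac myosin filaments, and Crybg2 rose (1.71 ± 0.32, 1.54 ± 0.37, 1.96 ± 0.45 and 1.18 ± 0.23 in the authors' deposited table). Proximal tubule genes had 1 member falling, 1 rising and 17 not passing: the dicarboxylate transporter gene Slc13a3 fell and Gatm of creatine synthesis rose (-0.48 ± 0.079 and 0.46 ± 0.10 in the authors' deposited table). The lower list call (median -0.056, adjusted p = 0.0376) was lost at a preset correlation of 0.05 (adjusted p = 0.131) and by ranks (0.178), and its median did not stand out from 10000 random lists (permutation p = 0.120). Kidney injury genes were higher with 2 of 12 rising, the fibrinogen gene Fga and the osteopontin gene Spp1 (0.59 ± 0.092 and 0.44 ± 0.12 in the authors' deposited table; median 0.14, adjusted p = 0.000242). Podocyte genes were higher with 0 of 10 passing (median 0.10, adjusted p = 0.00616), while the lists for the loop and distal tubule and for the collecting duct did not pass (adjusted p = 0.0559 and 0.989). The first of these 2 was higher by ranks (0.0403) and with all features as background (0.0180). Secreted proteins known from hepatocytes had 3 members falling and 1 rising of 16: transthyretin (Ttr), Serpina1a and Serpina1c fell (-1.14 ± 0.12, -1.08 ± 0.16 and -0.68 ± 0.11 in the authors' deposited table). The Serpina1 genes are near-identical copies, and the list call (adjusted p = 0.000601) did not hold by ranks (0.350).

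S100a8 and S100a9 rose in kidney and 9 other neutrophil markers did not pass (1.24 ± 0.35 and 1.17 ± 0.31 in the authors' deposited table; list median 0.54, adjusted p = 8.47e-05). Interferon-stimulated genes were higher as a list with 0 of 33 passing (median 0.20, adjusted p = 1.87e-07). Per1 fell (-0.57 ± 0.15 in the authors' deposited table) and the clock genes were lower (median -0.26, adjusted p = 0.00475, or 0.0740 by ranks), although 6 of 17 lay above 0. Among immediate early genes Fos rose while Ccn2 and Ier3 fell (0.88 ± 0.21, -0.44 ± 0.10 and -0.50 ± 0.14 in the authors' deposited table), and the list did not pass (adjusted p = 0.735). Glucocorticoid targets had 2 members rising (Pdk4 and Angptl4) and 2 falling, Per1 and Tsc22d3 (-0.39 ± 0.11 in the authors' deposited table). Their list did not pass (adjusted p = 0.112, or 0.0493, higher, with all features as background). The stress-related genes Atf5 and Cryab rose and the matrix gene Mgp fell (0.35 ± 0.092, 0.36 ± 0.088 and -0.37 ± 0.10 in the authors' deposited table). Their lists were ATF4 targets, heat shock proteins and extracellular matrix genes, and none passed cameraPR (adjusted p = 0.283, 0.291 and 0.207). The matrix list's median was 0.049. Ribosomal protein genes (median 0.11), nuclear respiratory chain genes (0.081) and proliferation genes (0.19) were higher with no member passing (adjusted p = 0.000201, 0.000232 and 2.57e-05). Markers of neighbouring tissues differed as lists: adrenal markers were lower (median -6.82) and exocrine pancreas markers higher (median 6.33). Of their members 0 of 13 and 0 of 18 passed (cameraPR adjusted p = 1.23e-17 and 2.44e-15). With no value per mouse, neighbouring tissue left in few libraries cannot be told apart from an effect of the genotype. Fitted folds of these 2 lists are no bounds. Adipocyte markers were higher (median 0.18, adjusted p = 0.0376, or 0.120 with a preset correlation of 0.05). In all, 15 of 33 lists passed in kidney.

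In liver, genes of fatty acid synthesis fell and PPAR alpha targets rose. Of 18 fatty acid synthesis genes 6 fell and 12 did not pass, 13 fell when adjusted over the list alone, and the list's median was -0.69 (cameraPR adjusted p = 3.59e-15). Srebf1, the transcription factor gene that drives lipogenesis, Acly and Acss2, which make cytosolic acetyl-CoA, and the lipogenic regulator Thrsp had log2 fold changes of -1.06 ± 0.21, -1.12 ± 0.24, -0.86 ± 0.19 and -2.15 ± 0.49 in the authors' deposited table (adjusted p = 0.000150, 0.000716, 0.000927 and 0.00182), and Pklr and Scd1 also fell. Cholesterol synthesis genes were lower with 2 of 25 falling, Dhcr7 and Lss (-0.71 ± 0.15 and -0.53 ± 0.16 in the authors' deposited table), 8 when adjusted over the list alone (median -0.36, adjusted p = 2.38e-09). PPAR alpha targets had 6 of 29 members rising and 23 not passing: Fgf21, a hormone released by the liver in fasting, the fatty acid hydroxylase genes Cyp4a14, Cyp4a10 and Cyp4a31, and Acot1 and Acot2. Log2 fold changes were 2.38 ± 0.21 for Fgf21, 2.59 ± 0.24 for Cyp4a14, 1.64 ± 0.24 for Cyp4a10 and 1.51 ± 0.24 for Cyp4a31 in the authors' deposited table, the Cyp4a and Acot genes having close paralogs with which they may share reads. The list's median was 0.28 (adjusted p = 1.91e-17), and Pdk4 and Angptl4, which rose in kidney, had liver values of 1.25 ± 0.54 and 0.24 ± 0.21 in the authors' deposited table without passing.

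**Figure D2:**
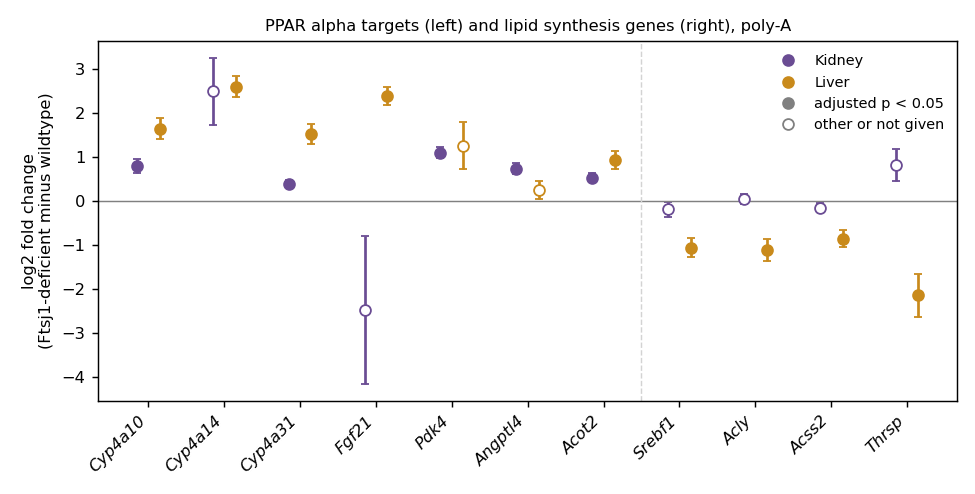
Log2 fold change (Ftsj1-deficient minus wildtype, n = 3 mice against 3) of 7 PPAR alpha targets and 4 lipid synthesis genes in poly-A libraries of kidney and liver, with bars of 1 standard error and filled points for an adjusted p under 0.05 in the authors' deposited table. Cyp4a10, Cyp4a31 and Acot2 rose in both organs, Srebf1, Acly, Acss2 and Thrsp fell in liver, and Fgf21 in kidney had a mean level of 3.18 normalised counts.

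The major urinary protein gene Mup7 and the cytochrome gene Cyp2d9 fell in liver (-2.94 ± 0.90 and -0.74 ± 0.19 in the authors' deposited table). The cytochrome genes Cyp2c69 and Cyp2c40 rose (2.99 ± 0.71 and 1.98 ± 0.25 in the authors' deposited table). The anion transporter gene Slc22a26 rose by 3.45 on the log2 scale by the authors' deposited table. Mup and Cyp2c genes are families of near-identical copies and are uncertain. Among the bile acid and xenobiotic cytochromes 2 rose (Cyp2c37 and Cyp2c38), 1 fell (Cyp2d9) and 23 did not pass, and the list was higher (median 0.24, adjusted p = 0.00229). The stress hormone gene Gdf15 rose (1.18 ± 0.24 in the authors' deposited table). With Fgf21 it made up the 2 members that rose of 25 ATF4 targets (6 adjusted over the list alone, median 0.26, adjusted p = 2.02e-06). Other large falls were the lipase-related gene Pnpla5 (-4.52 ± 1.05), the acetyltransferase-like gene Nat8f7 (-3.12 ± 0.35), Gldn (-2.39 ± 0.58) and the actin regulator Lmod2 (-2.20 ± 0.52) in the authors' deposited table, and other large rises were Acot5 (2.63 ± 0.52) and Unc79 (1.90 ± 0.42). Genes known from adipocytes were lower, with 5 of 14 falling: complement factor D (Cfd), the lipid droplet gene Cidec, Thrsp, Adrb3 and Car3 (Cfd -2.52 ± 0.53 and Cidec -0.75 ± 0.17 in the authors' deposited table; median -0.72, adjusted p = 5.47e-07). Gluconeogenesis and glycolysis genes were lower with 1 of 16 falling, the pyruvate kinase gene Pklr (-0.86 ± 0.21 in the authors' deposited table; median -0.20, adjusted p = 0.00630). Reg2, a gene known from the exocrine pancreas, had the largest rise in liver (8.90 ± 2.25 in the authors' deposited table, a fold that is no bound). Exocrine pancreas markers were higher with 0 of 18 passing and 1 adjusted over the list alone (median 5.87, cameraPR adjusted p = 5.10e-09). With no value per mouse, pancreas left in few liver libraries cannot be told apart from an effect of the genotype.

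Interferon-stimulated genes were higher in liver, with Ifit1 and Rsad2 rising of 33 tested members (0.57 ± 0.15 and 0.66 ± 0.18 in the authors' deposited table), 8 adjusted over the list alone, and a median of 0.25 (adjusted p = 3.84e-06). S100a8 and S100a9 rose (0.99 ± 0.24 and 0.88 ± 0.23 in the authors' deposited table), while 10 other neutrophil markers and the list did not pass (adjusted p = 0.116, or 0.00644, higher, with all features as background). Per2 of the clock fell (-1.11 ± 0.25 in the authors' deposited table). The clock list's lower call (median -0.30, adjusted p = 0.0136) was lost at a preset correlation of 0.05 (adjusted p = 0.0641) and by ranks (0.107), and 7 of 17 members lay above 0. Glucocorticoid targets had Fkbp5 rising and the feedback inhibitor gene Errfi1 falling (0.75 ± 0.21 and -1.19 ± 0.16 in the authors' deposited table), and the list did not pass (adjusted p = 0.373). Acute phase genes had Il1rn rising and Orm3 falling (0.85 ± 0.23 and -0.80 ± 0.23 in the authors' deposited table), with a list that did not pass (adjusted p = 0.206). Snhg11, Neat1, the ribonucleotide reductase gene Rrm2 and Col15a1 fell (-1.02 ± 0.15, -0.86 ± 0.25, -0.89 ± 0.23 and -0.67 ± 0.15 in the authors' deposited table). Nuclear respiratory chain genes were lower with 0 of 71 passing (median -0.12, adjusted p = 0.000218). Immediate early genes and proteins of small nucleolar ribonucleoproteins and rRNA processing were higher with no member passing (medians 0.22 and 0.088, adjusted p = 0.0161 and 0.00463). Both calls were lost with a preset correlation of 0.05 (adjusted p = 0.0952 and 0.0633). In all, 13 of 30 lists passed in liver.

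Neutrophil and macrophage markers were higher as lists in the spleen of the deficient mice and B cell markers were lower. The granule protease gene Prtn3, the eosinophil granule gene Prg2, the pattern receptor gene Clec4e, the galectin gene Lgals3 and the signalling adaptor gene Tyrobp rose, with log2 fold changes of 1.72 ± 0.36, 0.79 ± 0.17, 1.14 ± 0.27, 0.67 ± 0.15 and 0.66 ± 0.15 in the authors' deposited table. Wfdc21, Wfdc17, the small heat shock protein gene Hspb1 and Msrb1 rose too (1.44 ± 0.31, 1.16 ± 0.26, 1.10 ± 0.18 and 0.58 ± 0.13 in the authors' deposited table), as did 2 light chain segments, which are uncertain for shared reads. Mef2c, a transcription factor gene of B cells among others, and the sodium channel gene Scn11a fell (-0.59 ± 0.14 and -0.84 ± 0.19 in the authors' deposited table). Neutrophil markers had 1 of 16 members rising, 8 adjusted over the list alone and a median of 1.10 (cameraPR adjusted p = 6.37e-14); S100a8 and S100a9 did not pass there (adjusted p = 0.296 and 0.213 in the authors' deposited table). Macrophage markers (median 0.32), natural killer and cytotoxic markers (0.31) and erythroid genes (0.40) were higher with no member passing over all genes (adjusted p = 0.000135, 0.00291 and 0.000135). B cell markers were lower, with 0 of 13 members passing and 5 falling when adjusted over the list alone (median -0.19, adjusted p = 2.49e-05), while T cell and plasma cell markers did not pass (adjusted p = 0.658 and 0.131). With all features as background the plasma cell list was higher (0.0451).

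Metabolic and stress lists also differed in spleen although almost no member passed. PPAR alpha targets (median 0.28), interferon-stimulated genes (0.20), nuclear respiratory chain genes (0.24), immediate early genes (0.16), extracellular matrix genes (0.23) and endoplasmic reticulum chaperones (0.23) were higher with 0 members passing. Their adjusted p were 1.19e-05, 1.19e-05, 2.39e-06, 0.00252, 0.00436 and 0.00510 by cameraPR. Mitochondrially encoded genes (median -0.17) and nuclear and imprinted long non-coding RNAs (-0.15) were lower (adjusted p = 0.00252 and 0.00314). ATF4 targets (0.20) and heat shock proteins (0.084, with Hspb1 rising) were higher and cholesterol synthesis genes (-0.085) lower, at adjusted p of 0.0239, 0.0250 and 0.0481. These 3 calls were lost with a preset correlation of 0.05 (adjusted p = 0.116, 0.103 and 0.171), and the heat shock call also by ranks (0.0703). The heat shock median did not stand out from 10000 random lists (permutation p = 0.298). Exocrine pancreas markers were abundant in the spleen libraries, with a median level of 284224 normalised counts. All 18 tested lay above 0 (median 0.34), and their list did not pass (adjusted p = 0.725 by cameraPR). Whether tissue of the pancreas contributed to the higher lists, such as the chaperones, was not tested. In all, 16 of 32 lists passed in spleen.

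Long non-coding RNAs were called most often in heart and liver of the rRNA-depleted libraries. By the authors' deposited table, 1 lncRNA passed in brain (0 rose, 1 fell), 40 in heart (17 rose, 23 fell), 15 in kidney (1 rose, 14 fell), 37 in liver (10 rose, 27 fell) and 0 in spleen, where 245 had an unadjusted p under 0.05 by DESeq2. With adjustment over the 5 organs together 20 passed in heart and 2 in spleen. Kidney held Cdr1 and Cdr1os, overlapping transcripts of opposite strand, which fell by 1.39 and 1.37 on the log2 scale by the authors' deposited table (adjusted p = 1.19e-09 and 1.82e-12). Whether counting used the strand is not given in the sources used here, so reads of one may be counted for the other. Gm49692, Gm30551 and Gm15895 fell in kidney and Halr1, transcribed beside the Hoxa cluster, rose (-2.04 ± 0.22, -1.84 ± 0.18, -1.48 ± 0.20 and 0.68 ± 0.17 in the authors' deposited table). In liver BC049987, Gm31121 and Gm12718 fell and Gm32540 and 9030619P08Rik rose (-2.09 ± 0.41, -3.32 ± 0.40, -3.15 ± 0.38, 1.68 ± 0.28 and 1.77 ± 0.25 in the authors' deposited table). Heart had falls of 6330576A10Rik and A530020G20Rik and rises of Gm48626 and 2900052N01Rik (-4.12 ± 0.91, -2.28 ± 0.46, 1.63 ± 0.27 and 1.61 ± 0.37 in the authors' deposited table), and Gm13648 fell in brain (-2.60 ± 0.55).

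lncRNAs measured in both library kinds changed in like directions where both called them. Of those called by both tables, 4 in heart, 5 in kidney and 14 in liver had the same direction and 0 opposite ones, against 0.0800, 0.0419 and 0.332 for independent calls. Gm48626 and 2900052N01Rik in heart, Gm49692, Gm30551, Gm15895 and Halr1 in kidney, and BC049987, Gm31121, Gm12718 and Gm32540 in liver were among them. Across lncRNAs with a mean level of 10 or more in both kinds, Pearson's r of the log2 fold changes was 0.0895 in brain, 0.211 in heart, 0.247 in kidney, 0.562 in liver and 0.291 in spleen. The 2 kinds come from the same organs of the same mice, lncRNAs are not independent replicates, and r was larger in each organ at a mean level of 100 or more, up to 0.818 in liver.

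Small nucleolar RNAs, which guide chemical modification of ribosomal RNA, and spliceosomal small nuclear RNAs gave no call in any organ. At a mean level of 10 or more, median standard errors of log2 fold changes were 0.37 to 0.55 over the organs for snoRNAs. They were 0.48 to 0.64 for snRNAs and 0.13 to 0.24 for poly-A genes. Detection was simulated for poly-A genes only, so changes of moderate size may have gone uncalled here. DESeq2's adjusted p passed for 0 snoRNAs in brain, heart, kidney, liver and spleen, with 25, 17, 10, 8 and 4 at an unadjusted p under 0.05, and for 0 snRNAs, with 10, 9, 4, 5 and 12. Among the 3 smallest p of each table were those of Snord14e in kidney and of Rnu5g, a U5 gene, in heart (-0.64 ± 0.28 and -0.71 ± 0.31 in the authors' deposited table), and neither passed. As a class, H/ACA snoRNAs, which guide pseudouridylation, were higher in kidney (median 0.14 over 39, cameraPR adjusted p = 0.00342) and predicted snoRNAs lower (median -0.00037 over 261, adjusted p = 0.0378). C/D snoRNAs, which guide ribose methylation, were higher in spleen (median 0.074 over 87, adjusted p = 0.0449), a call lost when all features with a statistic were used (adjusted p = 0.0615), and did not pass elsewhere. U1 genes were lower in brain (median -0.46 over 4 genes, adjusted p = 0.00510) and did not pass in the other organs. With a preset correlation of 0.05 the kidney and spleen snoRNA calls were lost (adjusted p = 0.0646, 0.271 and 0.398) and the U1 call held (0.00881). None of these 4 class medians stood out from 10000 random lists matched on level (permutation p = 0.429, 0.315, 0.0686 and 0.0516 in the order given).

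tRNA identifiers passed in heart and liver. By the authors' deposited table, 21 identifiers fell and 0 rose in heart, 13 rose and 15 fell in liver, and 0 passed in brain, kidney and spleen, where 98, 65 and 45 had an unadjusted p under 0.05 by DESeq2. The heart identifiers had high mean levels, from 5730 to 113586 normalised counts, and log2 fold changes between -0.77 and -0.68; URS000043D29E_10090 fell by 0.77 on the log2 scale by the authors' deposited table (SE 0.19). Liver identifiers ranged from -2.76 for URS000005A7A9_10090 to 2.34 in the authors' deposited table, with URS000033E68A_10090 among those that rose. Many identifiers carry the same values as others, so the 21 of heart held 6 distinct sets of values and the 28 of liver 16, and the tables do not pair identifiers with amino acids or anticodons. With identical entries taken once, an alternative chosen after seeing the data, 2 passed in heart and 15 in liver, and with adjustment over every identifier with a p-value 0 passed in heart and 14 in liver. Adjusted over the 5 organs together, 0 identifiers passed in either organ.

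Several genes changed in the same direction in more than 1 organ. Apart from Ftsj1, 28 poly-A genes did so (15 rose, 13 fell), and S100a8 and S100a9 rose in heart, kidney and liver. At an adjusted p under 0.1 the count was 43. With a log2 fold change of at least 1 as well as an adjusted p under 0.05 it was 7, with S100a8 and S100a9 left in fewer than 3 organs. Kidney and liver shared 10 genes that rose, among them Acot1, Acot2, Cyp4a10, Cyp4a31, Gatm and Slc22a26, against 0.586 for independent lists (Fisher's exact test, one-sided, adjusted p = 1.91e-08 over the tests of this family). They shared 9 that fell against 1.64 (adjusted p = 0.000810). Heart and kidney shared 5 that rose, with Pdk4, Angptl4, S100a8 and S100a9 among them, against 0.131 (adjusted p = 5.93e-06). Heart and liver shared 3, S100a8, S100a9 and Slfn4, against 0.299 (adjusted p = 0.0493). Per1 fell in heart and kidney, Atf5 rose in brain and kidney, and 1 lncRNA, Gm20400, fell in heart and kidney. The organs came from the same 6 mice, so the comparisons are not independent and part of this overlap may reflect differences between individual mice. Interferon-stimulated genes were higher as a list in each of the 5 organs, while ribosomal protein genes were lower in brain and higher in heart and kidney, and nuclear respiratory chain genes lower in brain and liver and higher in heart, kidney and spleen.

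The change itself differed between organs for part of the features. Cochran's Q over the 5 organs' log2 fold changes passed for 212 of 17367 poly-A genes, 25 of 4112 lncRNAs and 11 of 538 tRNA identifiers, and for 0 of 234 snoRNAs and 0 of 148 snRNAs, of which 2 and 3 had an unadjusted p under 0.05. The 11 tRNA identifiers held 2 distinct sets of values. With all features used, 0 tRNA identifiers passed and 94 had an unadjusted p under 0.05 by Cochran's Q. Among the poly-A genes that passed were Cntnap5a and Synpr, which fell in kidney (adjusted p = 1.44e-22 and 1.66e-10), Nat8f7, which fell in liver (2.12e-14), and Fos, which fell in brain and rose in kidney (2.51e-07). Passing in 1 organ and not in another does not by itself show a difference, and no such difference is claimed for genes outside this test.

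**Figure D3:**
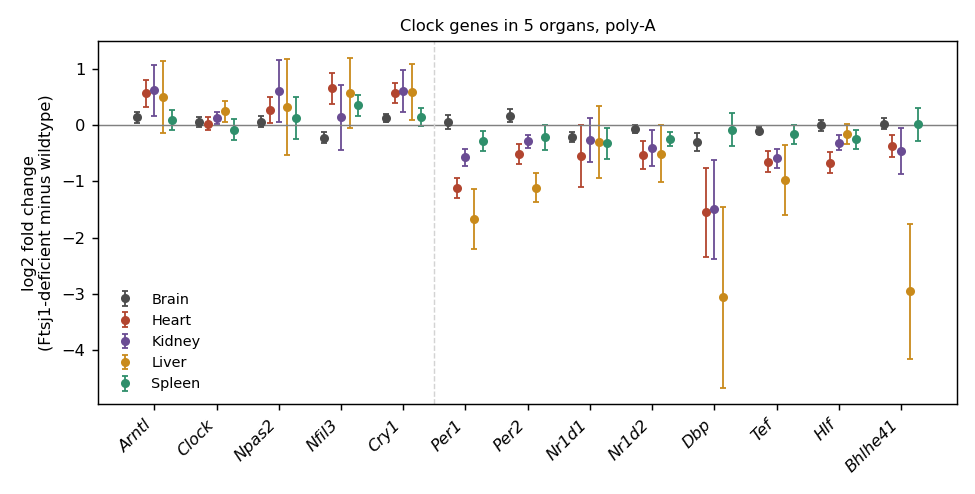
Log2 fold change (Ftsj1-deficient minus wildtype, n = 3 mice against 3) of 13 circadian clock genes in poly-A libraries of 5 organs, with bars of 1 standard error from the authors' deposited table. Per1 passed in heart (-1.12) and kidney (-0.57) and Per2 in liver (-1.11). Dbp and Bhlhe41 in liver had no adjusted p, and the other points did not pass.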

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

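Among the tests of explanations in this part, those on the clock, the feeding state, handling shared by all organs and red cell genes were chosen only after the result, or a part of it, was seen: Per1, Per2 and the medians of the clock and erythroid lists were known by then. Standard errors of medians in this part come from resampling the genes of a set. They measure the spread among genes and not among mice. For the globin genes the larger of this error and the median of the authors' standard errors was used.

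The change differed between organs, by Cochran's Q with Benjamini-Hochberg adjustment, for 212 poly-A genes, 25 lncRNAs and 11 tRNA identifiers, the last holding 2 distinct sets of values and none passing with all features. Each named gene below is one for which this test passed, and the value is its adjusted p. Kidney carried the most extreme change for Cntnap5a (1.44e-22), Synpr (1.66e-10) and Mybpc3 (0.00628), with log2 fold changes there of -2.40, -2.79 and 1.96 in the authors' deposited table. Liver carried it for Nat8f7 (2.12e-14), Errfi1 (0.000311), Thrsp (0.00453), Per2 (0.00704), Acly (0.0151), Acss2 (0.0245), Dhcr7 (0.0302), Acot2 (0.0393) and Unc79 (0.0397). Heart carried it for 3110045C21Rik (0.000431) and Hsd17b7 (0.00187), and spleen for Hspb1 (0.000231), Prtn3 (0.000848), Mef2c (0.0262) and Tyrobp (0.0262). Brain carried it for Arc (0.0142), Btg2 (0.0151), Junb (0.0219), Ccn1 (0.0228) and Ier2 (0.000829), all of which fell there. Fos (2.51e-07) fell in brain and rose in kidney, with a liver value of 1.95 in the authors' deposited table that did not pass there. Ier3 (0.00680) fell in kidney, and Elovl6 (0.00423) rose in kidney with a value of -1.36 in heart in the authors' deposited table. Pdk4 (4.15e-09) rose in heart and kidney and Per1 (0.000102) fell there. Their liver values of 1.25 and -1.67 in the authors' deposited table were the most extreme and did not pass there, and their brain values were -0.048 and 0.048. Nupr1 (0.00448) rose in brain and had a liver value of 3.32 in the authors' deposited table without passing there. Ftsj1 itself differed (0.00119), from -2.70 in brain to -3.51 in liver in the authors' deposited table. Among lncRNAs of the rRNA-depleted libraries the test passed for Gm49692 (1.09e-12), Gm30551 (1.61e-08), Cdr1os (0.000136) and Gm15895 (0.00164), which fell in kidney, Gm12718 (7.90e-09) and Gm31121 (9.09e-09), which fell in liver, and Gm32540 (0.0221), which rose in liver. Gm22146 (2.96e-05) rose in liver and fell in heart. It also passed for 6330576A10Rik (0.00325) and A530020G20Rik (0.00465), which fell in heart, for Gm49692 in the poly-A tables (1.79e-14), and for URS000043D29E_10090 (0.0266), which fell in heart.

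PPAR alpha targets were higher in kidney and in liver. Reads shared between paralogs are argued against as the whole cause, since without the Cyp4a and Acot families the median log2 fold change of the remaining 22 genes was 0.29 (SE 0.063) in kidney and 0.23 (SE 0.049) in liver, above all 10000 random lists. Of these 22, 6 passed the authors' threshold in kidney and 1, Fgf21, in liver, where the other calls were Cyp4a and Acot genes. A shift of the clock or of the hour of sampling may contribute: the median of 5 clock genes of the activator phase exceeded that of 8 of the repressor phase by 1.03 in kidney (exact permutation p = 0.00777) and 1.55 in liver (p = 0.0350), and the hour of sampling of each mouse is not given in the sources used here. The size of the clock difference did not follow the PPAR alpha list in heart and spleen. In heart it was 1.16 (exact permutation p = 0.00777), but the list did not pass (median 0.051, cameraPR adjusted p = 0.582). In spleen it was only 0.36, yet the list was higher with 0 members passing (median 0.28, cameraPR adjusted p = 1.19e-05). In brain neither passed (exact permutation p = 0.375, cameraPR adjusted p = 0.572). A different feeding state stays open, as 6 fasting-induced glucose genes had a liver median of 0.057 with an SE of 0.26, too wide to decide. The genotype as a cause is likewise open and cannot be separated from these with 3 mice against 3.

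Immediate early genes were lower in brain. Handling or time to freezing that was shared by all organs would lower them everywhere, but their medians were -0.17 in heart, -0.016 in kidney, 0.22 in liver and 0.16 in spleen, and the list was lower in heart (adjusted p = 0.0228, or 0.112 with a preset correlation of 0.05) and higher in liver (adjusted p = 0.0161, or 0.0952) and spleen (0.00252, or 0.0320). Fewer neurons in the sampled tissue are argued against by synaptic genes, whose median in brain was 0.040 (SE 0.014). Synaptic genes as a list do not show whether brain regions were represented equally in both genotypes. Striatal markers (median 0.12, 13 of 13 above 0) and pituitary markers (median -1.14) did not pass cameraPR (adjusted p = 0.0503 and 0.462). By ranks the striatal list was higher (adjusted p = 0.0113). Unequal sampling of regions therefore stays open, and handling that reached the brain alone was not tested. A lower activity of the immediate early genes in the deficient mice therefore remains a hypothesis.

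Neutrophil genes were higher in several organs. In spleen the list was also higher (median 1.10, cameraPR adjusted p = 6.37e-14). In brain it did not pass (median -0.11, cameraPR adjusted p = 0.960). The comparison with red cell genes was made in heart, kidney and liver only. Blood left in the organ would raise red cell genes with the neutrophil markers, whose median was 1.57 in heart, 0.54 in kidney and 0.43 in liver, the list passing in heart and kidney. The median of 4 globin genes was 0.45 (SE 0.20) in heart, 0.22 (SE 0.16) in kidney and 0.58 (SE 0.73) in liver, too uncertain in each to decide whether it reached 50% of the marker median, so blood left in the organ stays open. The level to reach, first set by S100a8 and S100a9 alone, and the error, first taken from the spread among the 4 genes, were replaced after their results were seen, which had counted against blood in heart and kidney and for it in liver. More neutrophils in the blood or tissue of the deficient mice, or a difference between the few mice of each group, could not be tested with these tables.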

How the results depend on the processing

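Among the alternatives here, taking tRNA entries with identical values once was chosen after seeing the data. No paired analysis was possible because the deposited tables hold no value per mouse; for the same reason edgeR and DESeq2 fits with other normalizations, leaving out each replicate, a litter block and a mouse block were not run. With adjustment over all 5 organs together, poly-A calls were 20 in brain, 251 in liver and 33 in spleen, lncRNA calls 20 in heart and 2 in spleen, and tRNA calls 0 in heart and 0 in liver. tRNA calls were 0 in heart and 14 in liver with adjustment over every identifier with a p-value, 11 in heart over those with a mean level of 10 or more, and 2 in heart and 15 in liver with identical entries taken once. With all features with a statistic as background, 0 snoRNA classes passed in spleen and 1 snRNA class in kidney, the minor spliceosome (adjusted p = 0.0481), and with all features 0 tRNAs differed between organs by Cochran's Q. Genes changed in several organs numbered 43 (poly-A) and 2 (lncRNAs) at an adjusted p under 0.1, and 7 and 0 at one under 0.05 with a log2 fold change of at least 1. At a mean level of 100 or more in both library kinds, r of lncRNA fold changes was 0.212 in brain, 0.506 in heart, 0.479 in kidney, 0.818 in liver and 0.539 in spleen. The cause of these differences was not tested. The remaining counts of changed features stayed within 1.5 times under these adjustments, and no list or class that passed reversed its direction: 11 list calls and 3 snoRNA class calls were lost with a preset correlation of 0.05, and by ranks 7 list calls were lost and 9 gained. With all features, 15 list calls were gained and 1 lost, cholesterol synthesis in spleen (adjusted p = 0.0526). The unknown depth of each library limits low-level features most, and fitted folds there are no bounds.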

Other observations

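The comparison of clock gene groups in this part was chosen only after Per1, Per2 and the medians of the clock list were seen.

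The circadian clock genes moved as opposed groups in heart, kidney, liver and spleen. In brain the difference between the groups did not pass, and whether this difference varied between organs was not tested. Genes whose transcripts peak with the clock's activators (Arntl, Clock, Npas2, Nfil3 and Cry1) had medians of 0.56 in heart, 0.60 in kidney, 0.50 in liver, 0.13 in spleen and 0.063 in brain over the authors' deposited table. Genes of the opposite phase (Per1, Per2, Nr1d1, Nr1d2, Dbp, Tef, Hlf and Bhlhe41) had medians of -0.60, -0.43, -1.04, -0.23 and -0.035 in the same order. The difference was 1.16, 1.03, 1.55, 0.36 and 0.10, with two-sided exact permutation p over 1287 groupings of the genes, adjusted over the 5 organs, of 0.0129, 0.0129, 0.0437, 0.0129 and 0.375. All 5 activator-phase genes lay above 0 and all 8 of the other phase below 0 in heart, kidney and liver. The counts were 4 and 7 in spleen and 4 and 5 in brain. Genes are not independent replicates, and of the single genes only Per1 in heart and kidney and Per2 in liver passed. Dbp (-3.06 ± 1.61) and Bhlhe41 (-2.95 ± 1.20) in liver had no adjusted p in the authors' deposited table.

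Some genes passed in opposite directions in different organs: 4 between kidney and liver, 2 between heart and kidney, 1 between heart and liver and 1 between brain and kidney, the last being Fos. Among lncRNAs Gm22146 rose in liver and fell in heart.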
